A study of Paralichthys olivaceus with 12 samples.

How the data were processed

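Small RNA from the spleen of Japanese flounder (Paralichthys olivaceus) was profiled in 12 libraries. Per the labels, fish of about 250 g kept at about 22 °C received an intramuscular injection of Streptococcus iniae, a Gram-positive bacterium that causes streptococcosis in farmed fish, or of phosphate-buffered saline. The spleen, a main site of fish blood filtering and immune response, was sampled 6 h or 24 h later. The 4 groups (control and infected at each time) held 3 libraries each, and all 12 were used. The labels do not say that the replicates are separate fish, so p-values of group comparisons measure the spread between these samples, which may be partly technical. Fisher's exact, hypergeometric and sign-flip tests take sequences or hairpins as units and do not measure that spread.

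Per the labels' protocols, total RNA was extracted with Trizol and libraries were made with a TruSeq small RNA kit. The deposited table has 1147 entries, each a mature miRNA on a hairpin, with 945 distinct mature sequences of 18 to 26 bases; 9 lines of the table had been emptied for this work. Per the file headers and the legend, the raw columns hold numbers of reads that the authors assigned by mapping to miRBase hairpins and mature miRNAs and to the genome, with predicted miRNAs kept under hairpin criteria. The legend describes only some of the mapping classes that the table uses. The aligner, the counting program and the genome build are not given in the sources used here, so scaffold positions below are those of the authors' table, and no gene annotation was matched to them. In the deposited raw columns the values are expected counts: the 186 sequences listed in several entries carried equal values in each, 43.2% of these values were fractional, and 83.7% of the fractional ones became whole (within 0.01) when multiplied by the number of entries. The second set of columns holds a normalised signal, per the file headers, which the values show to be the authors' counts multiplied by a single factor per library, from 0.8138 to 1.33. How that factor was set is not given in the sources used here.

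The comparisons had been planned for whole counts, so the expected counts were rounded, and each sequence was kept once with the share of a single entry. Library totals were 10717151 to 15659572 over all entries and 9146931 to 13121928 over unique sequences. Intervals and floors derived from counts cover counting error only, since amplified reads are not independent molecules. Of 945 sequences, 569 passed edgeR's filterByExpr by group. A single edgeR quasi-likelihood model (version 4.0.16 in R 4.3.3, robust, TMM factors) with a mean per group and 8 residual degrees of freedom was fitted to the 12 libraries. The 5 comparisons were infected against control at 6 h and at 24 h, 24 h against 6 h in controls and in infected fish, and the difference between both infection effects. Calls had a Benjamini-Hochberg adjusted p under 0.05. Levels are CPM (counts scaled to a common total) on TMM-scaled library sizes, standard errors are the log2 fold change divided by the square root of the F statistic, and errors of levels are standard deviations (SD).

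Names follow the authors' table: L and R with a number mark bases added or lost at the left and right end relative to the known miRNA, ss marks substitutions, p5 and p3 mark arms newly found in the data, and PC marks predicted miRNAs. The text names, for each infection comparison, up to 10 called sequences each way of largest change whose libraries did not overlap between the groups and whose mean was at least 10 CPM, up to 2 called members of each list, and, whatever their result, the most abundant forms of miR-21, miR-146, miR-155, miR-223, miR-142, miR-150, miR-451, miR-144, miR-462, miR-731, miR-122, miR-1 and let-7a. For the time comparisons and the difference of effects it names up to 5 each way. The comparisons, their tests, this rule, 25 lists of miRNAs and the alternatives other than those named as added were fixed before the data were examined; sequences outside the rule are named as examples chosen after their values were seen.

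The lists cover inflammation-induced miRNAs, the teleost interferon-associated pair miR-462 and miR-731, markers of blood, vessel, stroma and other tissues, and families such as let-7. Lists with at least 3 tested members (22 of 25) were tested with limma's camera (version 3.58.1) on log2 CPM with a prior count of 2 and a correlation preset at 0.01, adjusted over the lists of a comparison, with an estimated correlation and with fry as alternatives. Camera compares a list with the other sequences, and fry asks whether its members move 1 way on balance. Library shares of lists and of the most abundant entries were compared by two-sided exact permutation tests, in which 3 libraries against 3 cannot give a p under 0.1. Predicted and known miRNAs were compared by two-sided Fisher's exact tests.

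The calling step was tested on simulated counts with the real means, totals and spread, 200 of the sequences being changed. For the 6 h comparison it recovered 58.8% of 2-fold and 83.7% of 4-fold changes, with 8 unchanged sequences called (5.4% of calls, 545 tested). For the 24 h comparison it recovered 61.3% and 72.7%, with 6 unchanged sequences called (4.4%, 546 tested). The simulated changes were as many up as down, and each count was drawn independently. A scaling bias or a deviating library was thus not simulated, and the share of false calls may differ in the real data. The Benjamini-Hochberg adjustment is also more lenient when many sequences change than when few pass, as at 6 h (5 calls). Recovery there may thus be lower than in the simulation. The alternatives were DESeq2 (version 1.42.0), limma-voom, limma on the authors' normalised signal on the log2 scale with 1 added, other scalings and filters, fits of the compared groups alone, a replicate block, other treatments of repeated sequences and end variants, known miRNAs alone, and leaving out each library of the compared groups in turn. Summing the entries of a sequence and keeping sequences with identical counts once were added after seeing the data. End variants were summed by the name of the miRNA arm, so that sum also pools different sequences and loci of an arm, such as both miR-21-3p loci. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.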

Results

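The study asked how the spleen miRNA profile of Japanese flounder differs between bacteria-injected and saline-injected fish at an early and a later time. Library totals over all entries of the table ran from 10717151 (infected 24 h, replicate 3) to 15659572 (infected 6 h, replicate 1), and 592 to 685 distinct sequences were detected per library. The spleen was dominated by a few miRNAs. Counting each sequence once, let-7a-5p, a member of a family linked to cell differentiation, made up 13.89% ± 3.14 (SD, n = 12) of the counts, and miR-21-5p, an inflammation-induced miRNA, 10.34% ± 5.36. The endothelial miR-126-3p followed with 9.88% ± 1.74, the smooth muscle and fibroblast miR-143-3p with 7.79% ± 1.58, and the erythroid miR-451 with 5.5% ± 1.28. When the equal shares of repeated sequences were summed, miR-26a-5p, which has 4 entries, ranked next after miR-21-5p with 8.18% ± 0.98. Replicates differed by far more than counting error, with chi-square values per degree of freedom of 89.9 to 1244.1 between pairs of a group. On the first principal component (30% of the variance) infected 6 h replicate 1 lay at 5.53, apart from -4.42 and -4.78 of the other infected 6 h libraries, while the infected 24 h libraries lay between 8.47 and 18.95.

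At 6 h after injection, the comparison of infected with control spleens showed higher levels of 5 miRNAs, most of them the less abundant strand of their hairpin. PC-5p-1173_4682 (CTGATTTCATCTGGTGACATAGA), the 5p side of a miR-29 hairpin on scaffold NW_017859644.1 (19803318 to 19803410, plus strand), rose from 8.85 ± 1.52 to 75.6 ± 39.3 CPM (SD, n = 3). The 3p strand of miR-21 rose at both of its loci: hhi-mir-21-p3_1ss8AG (scaffold NW_017859664.1, 3092871 to 3092955, minus strand) from 6.92 ± 0.534 to 120 ± 105 CPM, and pol-miR-21-3p_1ss14AT (NW_017859651.1, 9552841 to 9552921, plus strand) from 24 ± 5.78 to 150 ± 94.5 CPM. The 3p strand of miR-146a, an miRNA induced by NF-kB that dampens Toll-like receptor signalling, rose from 69.4 ± 5.85 to 246 ± 71.5 CPM. A miR-128-5p form (ssa-miR-128-4-5p_R+2_1ss18AC), from a family abundant in neural tissue, rose from 1.23 ± 0.727 to 5.8 ± 1.08 CPM, a call that depended on the processing.

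These were the 5 calls among 569 sequences at 6 h (5 higher, 0 lower), with 73 at an unadjusted p under 0.05. Among lower sequences DESeq2 called 8 and limma-voom 0, while edgeR called 7 with a replicate block and 3 with at least 10 CPM. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the log2 fold changes were 3.09 ± 0.35 (SE, adjusted p = 0.0013) for PC-5p-1173_4682, 1.83 ± 0.22 (0.0013) for miR-146a-3p, 4.11 ± 0.56 (0.0029) and 2.65 ± 0.51 (0.035) for the miR-21-3p sequences and 2.22 ± 0.42 (0.033) for miR-128-5p. The guide strands did not pass: edgeR gave log2 0.84 ± 0.25 for miR-21-5p (adjusted p = 0.13), 0.93 ± 0.22 for miR-146a-5p (0.069) and 1.2 ± 0.36 for miR-155-5p (0.15; log2 0.54 without infected replicate 1). DESeq2 passed all 3 (adjusted p of 0.037, 0.0076 and 0.025). Infected replicate 1 held the highest level of each of these: 145619 CPM of miR-21-5p against 76783 and 69865, and 1543 CPM of miR-155-5p against 547 and 614. The groups did not overlap in 132 sequences (23.2%, where chance gives 10%). Without control replicate 3 or infected replicate 1 the count fell to 3, and without infected replicate 3 it was 10. The pol-miR-21-3p call was lost without any of the 3 controls or infected replicate 1, and the miR-128-5p call without control 2 or 3 or infected 1 or 2 (adjusted p up to 0.19 for each). The log2 fold change of pol-miR-21-3p was 1.96 without infected replicate 1, and its call was also lost with no filter (adjusted p = 0.084), when only the compared groups were fitted (0.064) and with known miRNAs alone (0.054). The miR-128-5p call was also lost on library size alone (adjusted p = 0.053), when only the compared groups were fitted (0.065) and with end variants summed (log2 0.45, adjusted p = 0.37). That sum pools it with another miR-128-5p sequence. The hhi-mir-21-p3 call was lost (adjusted p = 0.05) when only the compared groups were fitted. Its log2 fold change was 3.08 without infected replicate 1. With end variants summed it was 3.05, but that sum pools it with pol-miR-21-3p of the other locus.

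Other immune and blood miRNAs did not pass edgeR's test at 6 h. The granulocyte and monocyte miR-223 had a log2 fold change of 0.59 (adjusted p = 0.2), the leukocyte miR-142a-5p -0.11 (0.71), the lymphocyte miR-150 0.74 (0.41), the erythroid miR-451 and miR-144-3p 0.37 (0.56) and 0.31 (0.69). The teleost interferon-associated miR-462 and miR-731 had 0.01 (0.98) and 0.14 (0.69), the hepatocyte miR-122 0.7 (0.69), the muscle miR-1 0.81 (0.51; log2 0.05 without infected replicate 3) and let-7a-5p -0.27 (0.43).

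Among the lists at 6 h, inflammation-induced miRNAs shifted upward as a group: 3 of 33 members were called higher, 7 when adjusted over the list alone, and none lower, with miR-21-3p and miR-146a-3p as the called members (camera adjusted p = 1.3e-04; adjusted p = 0.65 with an estimated correlation; fry 0.12). Their share of the counts was 15.6% ± 6 in infected and 9.23% ± 0.72 in control libraries (exact permutation p = 0.1, the smallest possible, n = 3), and infected replicate 1 stood apart with 22.5% against 12.9% and 11.6%. The list of miR-10, miR-99, miR-100 and miR-125, which are linked to Hox and let-7 loci, lay lower with a median log2 fold change of -0.32 (camera adjusted p = 1.3e-04; adjusted p = 0.65 with an estimated correlation; fry 0.12); 0 of its 28 members passed over all sequences, and 1 higher and 2 lower when adjusted over the list alone. The sensory miR-183 cluster (3 members, 0 called, median 0.84) lay higher (0.048; adjusted p = 0.66 with an estimated correlation; fry 0.18), at a share of 0.00172% against 0.00108%. No other of the 22 tested lists passed camera at 6 h, and the neural list, with 1 of 18 members higher (miR-128-5p), had an adjusted p of 0.72.

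At 24 h the infected spleens differed in many more miRNAs, led by the inflammatory group. miR-155-5p (gga-miR-155_R+1, TTAATGCTAATCGTGATAGGGGT, scaffold NW_017859645.1, 2760609 to 2760666, plus strand), which promotes macrophage and lymphocyte activation, rose 8.87-fold from 396 ± 105 to 3514 ± 674 CPM (SD, n = 3). miR-21-5p (TAGCTTATCAGACTGGTGTTGGC, NW_017859651.1, 9552841 to 9552921, plus strand) rose 2.83-fold from 72500 ± 15786 to 204899 ± 16833 CPM, going from 7.41% ± 1.48 to 18.19% ± 1.53 of the counts. miR-146a-5p (NW_017859642.1, 11786564 to 11786669, plus strand) rose 2.87-fold from 39332 ± 8405 to 112788 ± 7903 CPM. miR-222a-3p, which targets a cell cycle inhibitor, rose 2.2-fold from 1305 ± 187 to 2867 ± 322 CPM, and miR-27c-5p (NW_017859695.1, 685832 to 685905, minus strand) 2.98-fold from 56.1 ± 5.75 to 167 ± 3.94 CPM. In the other direction, miR-20b-5p fell from 290 ± 120 to 92.5 ± 20.9 CPM, miR-18a-5p from 296 ± 81.5 to 113 ± 26.4 and miR-363-3p from 30.5 ± 5.59 to 8.48 ± 1.19. These belong to paralogs of the proliferation-associated miR-17-92 cluster.

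**Figure D1:**
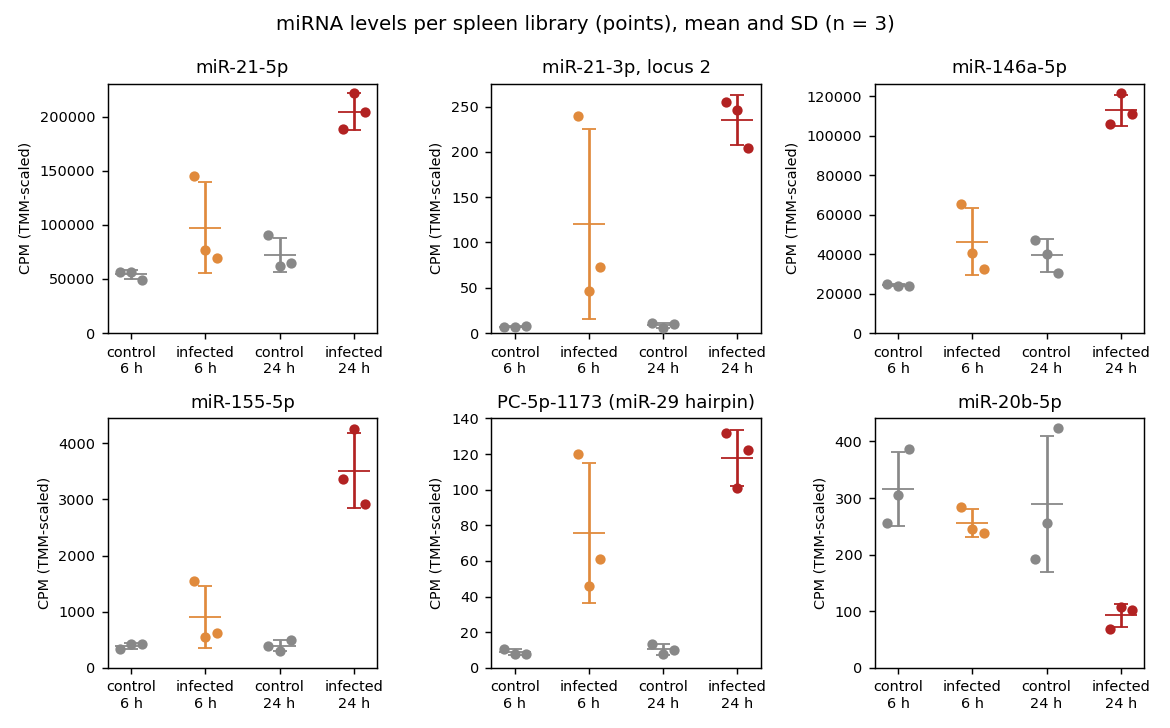
Levels of 6 miRNAs in CPM (TMM-scaled, linear axes from 0) in each of 12 spleen libraries, grouped as control and infected at 6 h and 24 h. Points are libraries, horizontal lines means and bars SD (n = 3). The 3 infected libraries at 24 h lie above all controls of that time for miR-21-5p, miR-21-3p, miR-146a-5p, miR-155-5p and PC-5p-1173 and below them for miR-20b-5p. Infected replicate 1 is the highest point at 6 h in the first 5 panels (1543 CPM for miR-155-5p).

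In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 89 of 569 sequences were called at 24 h (56 higher, 33 lower; 174 at an unadjusted p under 0.05). All 89 were among the 182 sequences (32%, chance 10%) whose infected and control libraries did not overlap. TMM scaling moved all log2 fold changes upward by 0.21 relative to library size alone. On library size alone 118 were called, 34 higher and 84 lower, which is 28.8% higher against 62.9%. The count fell to 40 without control replicate 2, 48 without infected replicate 2 and 47 without infected replicate 3. Of 42 named calls, 24 held whichever of the 6 compared libraries was left out, and none changed sign. On library size alone the rises of miR-181b-5p, miR-144-5p, miR-15c-3p, miR-15c-5p, let-7i-3p and miR-30b-3p did not pass. When only the compared groups were fitted, 45 were called. The calls of miR-2188-3p, miR-23a-5p, miR-7641-3p, miR-190a-3p, miR-101b-3p, miR-148a-3p, miR-148a-5p, miR-126-3p, miR-199a-3p and miR-30c-5p did not pass then. The same held for 1 of the miR-29b forms named below (adjusted p = 0.066) and for the 6 rises just named.

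The rises included both strands of miR-21, miR-146a and miR-155. By edgeR, hhi-mir-21-p3_1ss8AG had a log2 fold change of 4.73 ± 0.57 (SE, adjusted p = 6.1e-04, or 2.87 when summed by arm, pol-miR-21-3p included), PC-5p-1173_4682 3.5 ± 0.36 (2.5e-04), miR-155-5p 3.15 ± 0.39 (6.1e-04) and pol-miR-21-3p 2.17 ± 0.49 (0.014). The last had 2.9 without control replicate 1, and its call was lost without control replicate 2 (0.072) and with no filter (0.057). PC-3p-6526_344, on the 3p side of the miR-155 hairpin and chosen after its value was seen, had 3.25 ± 0.55 (0.0031). The guide strands had 1.52 ± 0.23 for miR-146a-5p (0.0019) and 1.5 ± 0.25 for miR-21-5p (0.0028). miR-27c-5p, the less abundant strand of its hairpin, had 1.57 ± 0.14 (9.2e-05). miR-146a-3p had 1.43 (0.0019) and PC-3p-994_5939, which is its sequence with 1 more base, 1.22 (0.0095). miR-2188-3p had 1.18 (0.011), lost without control 2 or infected 2 (up to 0.066), and miR-222a-3p 1.14 (5.8e-04).

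Several miR-17-92 paralogs fell. By edgeR, PC-3p-896_7198, which is miR-363-3p with 1 more base, had a log2 fold change of -1.87 ± 0.23 (adjusted p = 6.1e-04), miR-363-3p -1.84 ± 0.28 (0.0019), miR-19b-3p -1.66 ± 0.26 (0.0019), miR-20b-5p -1.65 ± 0.28 (0.0031) and miR-18a-5p -1.38 ± 0.27 (0.0072). ssa-miR-20b-5p_R-3_1ss1CA, the miR-20b-5p sequence without its last 3 bases, had -1.84 ± 0.37 (0.0081). Both strands of miR-7641, a sequence that also occurs in 5S ribosomal RNA, fell by 1.37 (0.0045) and 1.25 (0.033). miR-190a-3p, miR-101b-3p and miR-148a-3p had -1.16 (0.012), -0.9 (0.012) and -0.87 (0.027). The call of miR-101b-3p was lost without infected replicate 2 (0.053), that of miR-190a-3p without control 2 or infected 2 (up to 0.054), that of miR-148a-3p without control 2 or infected 2 or 3 (up to 0.081) and that of miR-7641-3p without control 1 or 2 or infected 2 or 3 (up to 0.11).

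**Figure D2:**
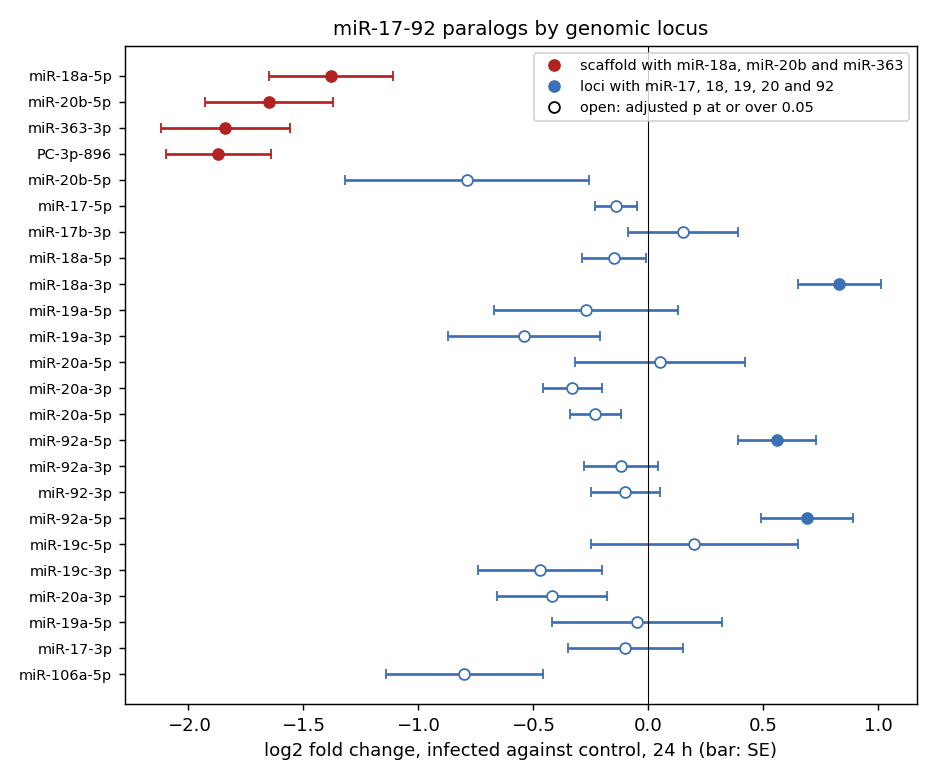
log2 fold changes (x axis, points; bars are SE) of infected against control spleens at 24 h for sequences of the miR-17-92 paralogs at the loci named here, ordered by locus. List members placed elsewhere are not drawn, among them ssa-miR-20b-5p_R-3_1ss1CA, which was called lower with -1.84. The 4 sequences of the scaffold with miR-18a, miR-20b and miR-363 (red) lie between -1.87 and -1.38 and were called lower, under TMM and on library size alone. The 20 sequences of the loci with miR-17, miR-18, miR-19, miR-20 and miR-92 (blue) have a median of -0.13; 3 of them were called higher, whereas 1 was higher and 3 lower on library size alone. Open points did not pass.

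In the list of inflammation-induced miRNAs, 13 of 33 members rose at 24 h and none fell, with 17 higher and 2 lower when adjusted over the list alone. The 13 were forms of miR-21, miR-146a, miR-155, miR-221 and miR-222, among them miR-221-3p with a log2 fold change of 0.87 (edgeR adjusted p = 0.0026). The median was 0.62 (camera adjusted p = 8.0e-05; adjusted p = 0.79 with an estimated correlation; fry 0.0052). The counts were 10 higher and 2 lower on library size alone, with a median of 0.43. The whole list held 29.7% ± 2.4 of the counts in infected and 12.2% ± 2 in control libraries (exact permutation p = 0.1, the smallest possible, n = 3). In the miR-23/24/27 clusters, which act in vessels and in T cells, 10 of 33 members rose and 1 fell, with 11 and 2 when adjusted over the list alone. miR-27c-5p rose by 1.57, and miR-23a-5p by 1.47 (0.02, lost without control 2 or infected 1 or 3, up to 0.062). Camera gave an adjusted p of 0.03 for this list (adjusted p = 0.79 with an estimated correlation; fry 0.021), but on library size alone 3 were higher and 4 lower and the median turned from 0.13 to -0.08. In the miR-15/16 family, which restrains the cell cycle, 3 of 10 members rose, 6 when adjusted over the list alone, such as miR-15c-3p by 0.71 (0.017) and miR-15c-5p by 0.51 (0.038). Camera gave 0.03 (adjusted p = 0.79 with an estimated correlation; fry 0.044), and on library size alone 0 were called with a median of 0.26. The miR-15c-3p call was lost without control 1 or 2 or infected 2 or 3 (up to 0.11), and the miR-15c-5p call without any compared library but control 3 (up to 0.21).

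The family of miR-148 and miR-152, which targets DNA methyltransferase and antigen presentation genes, fell in 4 of 6 members, and in 4 when adjusted over the list alone, with a log2 fold change of -1.67 for miR-148a-5p (edgeR adjusted p = 0.024, lost without control 2 or infected 2 or 3, up to 0.11), -0.87 for miR-148a-3p and -0.73 for miR-152-3p (0.0019). Camera gave an adjusted p of 0.018 (adjusted p = 0.79 with an estimated correlation; fry 0.021), and the family's share was 0.226% ± 0.02 in infected against 0.442% ± 0.078 in control libraries (exact permutation p = 0.1, n = 3). Part of that fall may come from the larger share of inflammation-induced miRNAs, since shares are parts of a fixed total. At 6 h the share was 0.322% ± 0.023 in infected and 0.324% ± 0.036 in control libraries. From 6 h to 24 h the list's median log2 change was 0.45 in controls and -0.31 in infected libraries. In controls 4 members were higher when adjusted over the list alone (camera adjusted p = 0.11). Part of the fall at 24 h may thus lie in a higher control level at that time. In the miR-17-92 list 3 of 40 members rose and 5 fell, the same counts when adjusted over the list alone (camera 0.056; adjusted p = 0.83 with an estimated correlation; fry 0.28). On library size alone 1 rose and 8 fell, with a median of -0.35 instead of -0.14, and with RLE factors 1 rose and 5 fell.

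Some markers of vessels and stroma were called lower in the infected spleens at 24 h. The endothelial miR-126 made up 8.06% ± 0.41 of the counts against 12.3% ± 0.76 in controls, and stromal and smooth muscle miRNAs 7.62% ± 0.81 against 12.2% ± 1.4 (exact permutation p = 0.1 for each, the smallest possible, n = 3). Shares are parts of a fixed total, and inflammation-induced miRNAs held 29.7% in infected against 12.2% in control libraries. That alone lowers the other shares, so the falls of these shares, and of the let-7 share below, need not reflect lower levels. By edgeR, miR-126-3p fell by 0.41 on the log2 scale (adjusted p = 0.034), miR-143-3p by 0.53 (0.015) and miR-199a-3p by 0.51 (0.018), and each call was lost without control replicate 2 (0.1, 0.053 and 0.071). The miR-199a-3p call was also lost without control 1 or infected 2 (0.054 for each), and the miR-126-3p call without any compared library but control 3 (up to 0.1). Of 4 endothelial members 1 was lower, 3 when adjusted over the list alone (camera 0.056; fry 0.021; adjusted p = 0.79 with an estimated correlation), and of 25 stromal members 2 were lower by either adjustment (camera 0.032; adjusted p = 0.79 with an estimated correlation; fry 0.079). The numbers of lower members in these lists were 3 and 10 on library size alone. The let-7 family held 15.9% ± 1.3 against 20.6% ± 2.8 of the counts (exact permutation p = 0.1, n = 3), yet 2 of its 36 members rose and none fell, let-7h-3p by 0.83 (0.0021) and let-7i-3p by 0.73 (0.043, lost without any compared library but control 3, up to 0.2). Adjusted over the list alone 1 rose. Between 6 h and 24 h let-7h-3p changed by log2 -0.82 in controls (edgeR adjusted p = 0.016) and by 0.31 in infected libraries. Its rise at 24 h is thus relative to a lowered control level. Scaled by library size alone, 1 rose and 5 fell, with a median of -0.27 instead of -0.06. Camera gave 0.97 for this list.

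Few blood cell markers were called at 24 h. By edgeR, the leukocyte miR-142a-5p fell by 0.55 on the log2 scale (adjusted p = 0.0081) as the only called member of 7 in the myeloid list, while miR-223 had 0.24 (0.48). Of 11 lymphoid members miR-181b-5p rose by 0.41 (0.044, lost without any compared library but control 3, up to 0.23, and when adjusted over the list alone), and miR-150 had -0.94 (0.095). Of 6 erythroid members miR-144-5p rose by 0.89 (0.027, lost without control 2 or 3 or infected 2 or 3, up to 0.18), with 0.56 (0.14) for miR-451 and 0.34 (0.46) for miR-144-3p. Of 7 interferon-associated members 0 were called in edgeR and 4 were higher when adjusted over the list alone, with 0.29 (0.057) for miR-462 and 0.31 (0.096) for miR-731. Adjusted over the list alone, 1 myeloid member was higher and 1 lower, and 1 erythroid member was higher. On library size alone the calls were 2 lower in the myeloid, 3 lower in the lymphoid and 1 lower in the interferon-associated list, with 0 higher in these and 0 called in the erythroid list. Camera gave adjusted p-values of 0.61, 0.61, 0.3 and 0.41 for these lists.

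Other families and tissues gave few calls at 24 h. The neural list rose in 2 of 18 members, both miR-128-5p, with log2 fold changes of 2.75 ± 0.44 (edgeR adjusted p = 0.0021) and 1.36 ± 0.27 (0.0068), and 1.8 with the sequences of this arm summed. In the list of miR-10, miR-99, miR-100 and miR-125, miR-125b-3p (dre-miR-125b-2-3p_L+1_1ss15CT) rose by 1.02 (0.0057), lost with the sequences of its arm summed (0.38, adjusted p = 0.13), and 2 of 28 members were lower, among them miR-100-3p with -0.77 (0.0061). Of 8 miR-29 members, which restrain collagen production, 2 forms of miR-29b fell, with -0.88 (0.0027) and, for ssa-miR-29b-3p, -0.69 (0.0095; 0.066 when only the compared groups were fitted). Of 13 miR-30 members miR-30c-5p fell by 0.55 (0.013, 0.063 without control 2), and miR-30b-3p rose by 0.4 (0.035, lost without any of the 6 libraries, up to 0.16). On library size alone 2 neural members were higher and 1 lower, 1 and 6 in the list of miR-10, miR-99, miR-100 and miR-125 (median -0.33 instead of -0.13), 0 and 3 for miR-29 and 0 and 4 for miR-30. Camera gave adjusted p-values of 0.61, 0.34, 0.22 and 0.51 for these lists. No member passed in the epithelial (10), striated muscle (3), liver (1), gut and kidney (2), pancreas (9), sensory (3), miR-130 family (8) or hypoxia and p53 (6) lists, where the hepatocyte miR-122 had -0.64 (0.56; log2 -1.44 without infected replicate 1) and the muscle miR-1 -0.39 (0.65), and no miR-430 was tested. let-7a-5p had -0.21 (0.33).

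A few called sequences had 0 counts in all 3 control libraries at 24 h, so their infected means were set against a floor of 3 counts per library (0.26 CPM). The floor covers the counting error of the controls alone, so these folds are no strict lower bounds. Relative to the floor, PC-3p-14063_123 was 20-fold higher in infected spleens (5.18 CPM), PC-5p-31619_36 9-fold, PC-5p-13606_129 4.55-fold and mmu-mir-3535-p3 3.56-fold. The last had 8, 13 and 3 counts in the infected libraries, so replicate 3 lay at the floor itself. PC-5p-13606_129 had 14, 11 and 5 counts there, against 11, 25 and 28 in the control 6 h libraries. These 4 were chosen after their values were seen. Predicted miRNAs were called at 24 h in 14 of 85 cases (16.5%) and known ones in 75 of 484 (15.5%), an odds ratio of 1.08 (95% interval 0.531 to 2.05, Fisher's exact p = 0.87). The classes differ in abundance, with a median of 2.51 CPM for predicted and 20.4 CPM for known sequences. They are not independent either, since some predicted sequences are known miRNAs with 1 more base. At 6 h the counts were 1 of 85 and 4 of 484 (odds ratio 1.43, Fisher's exact p = 0.56), but with at least 10 CPM the odds ratio was 8.14 (Fisher's exact p = 0.016).

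The 10 most abundant entries took 68.5% ± 0.088 of the counts in infected and 63.8% ± 1 in control libraries at 24 h, and 63.7% ± 1.4 and 61.4% ± 0.33 at 6 h (exact permutation p = 0.1 for each, the smallest possible, n = 3). The most abundant entry of each library, which need not be the same miRNA, took 18.2% ± 1.5 against 13.8% ± 1.6 at 24 h and 15% ± 0.27 against 17.7% ± 1.6 at 6 h (0.1 for each). Over the 52 comparisons of shares the smallest adjusted p was 0.23.

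The infection comparisons at 6 h and 24 h use different controls, and all 5 sequences called at 6 h were also called higher at 24 h (0.492 expected for independent lists, exact hypergeometric p = 7.8e-06 across sequences, which are not independent replicates). These were the miR-21-3p forms, miR-146a-3p, miR-128-5p and PC-5p-1173_4682. Both lists come from a single fit in which each sequence has a shared estimate of spread over the 12 libraries. A low estimate favours a call at both times, so the lists are not independent and the hypergeometric p-value may be too small. Of the 89 sequences called at 24 h, 64 (71.9%, where chance gives 50%) had the same sign at 6 h, and those higher at 24 h had a median log2 fold change of 0.22 at 6 h and 1.02 at 24 h. Across all 569 sequences the fold changes correlated with r = 0.25 and rho = 0.23. The shared count was 3 without control 6 h replicate 2 or 3, infected 6 h replicate 1 or any infected 24 h library, and 9 without control 24 h replicate 1 or infected 6 h replicate 3.

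**Figure D3:**
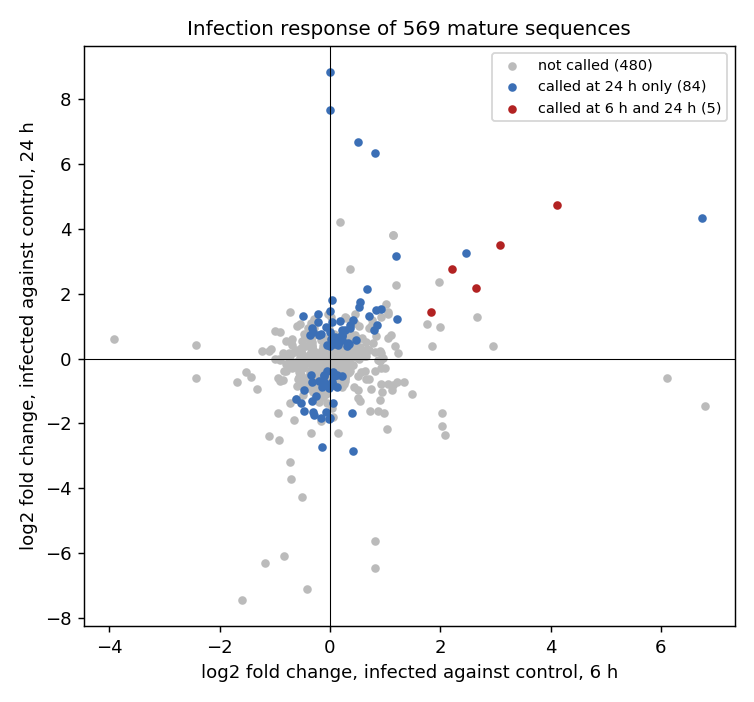
log2 fold changes of infected against control spleens at 6 h (x axis) and 24 h (y axis) for 569 mature sequences. Red points are the 5 sequences called at both times, blue points those called at 24 h alone and grey points those not called. The 4 points above log2 6 on the y axis had 0 counts in the controls of that time.

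The control spleens give the background of time and handling between 6 h and 24 h. In them the 3p forms of let-7b and let-7h and the miR-17-92 member miR-92a were lower at 24 h, whereas miR-181b-3p, from a family that tunes lymphocyte signalling, was higher. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, miR-181b-3p had a log2 fold change of 0.92 ± 0.19 (SE, adjusted p = 0.037), let-7b-3p -0.91 ± 0.2 (0.046), let-7h-3p -0.82 ± 0.13 (0.016), miR-92a-3p -0.8 ± 0.16 (0.036), a second miR-92-3p form -0.78 ± 0.15 (0.036) and miR-181a-5p -0.52 ± 0.11 (0.046). In all, 11 of 569 sequences passed (1 higher, 10 lower; 92 at an unadjusted p under 0.05), or 4 higher and 10 lower with RLE factors, and 113 did not overlap (19.9%, chance 10%). No list passed camera, with 3 of 36 let-7 members lower (8 lower and 1 higher when adjusted over the list alone; adjusted p = 0.33) and 3 of 40 miR-17-92 members lower (0.82). None of these named calls held whichever of the 6 compared libraries was left out. The count was 0 in edgeR without control 6 h replicate 2 or 3 or control 24 h replicate 1 or 2 (67 to 75 at an unadjusted p under 0.05), 20 without control 6 h replicate 1 and 39 without control 24 h replicate 3, and DESeq2 called 56. It was also 0 in edgeR when only the control groups were fitted (73 at an unadjusted p under 0.05).

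Between 6 h and 24 h in infected spleens the guide strands of miR-155, miR-146a and miR-21 rose. miR-155-5p went from 901 ± 557 to 3514 ± 674 CPM (SD, n = 3), a log2 fold change of 1.96 ± 0.37 (SE, edgeR adjusted p = 0.02), or 2.6 without infected 6 h replicate 1. miR-146a-5p rose by 1.29 ± 0.23 (0.016), miR-21-5p by 1.07 ± 0.25 (0.046), miR-27c-5p by 1.01 ± 0.13 (0.0052) and miR-222a-3p by 0.84 ± 0.13 (0.009). The miR-21-3p forms (0.97 with an adjusted p of 0.34, 0.8 with 0.43) and miR-146a-3p (-0.16, 0.74) did not pass. Several miR-17-92 paralogs fell, with -1.62 ± 0.23 (0.0052) for PC-3p-896_7198, -1.58 ± 0.28 (0.016) for miR-363-3p, -1.47 ± 0.28 (0.02) for miR-20b-5p, -1.24 ± 0.27 (0.041) for miR-18a-5p and -1.05 ± 0.25 (0.047) for miR-19b-3p.

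In edgeR's test 19 sequences passed between the infected groups (10 higher, 9 lower; 88 at an unadjusted p under 0.05), 149 did not overlap (26.2%, chance 10%), and TMM moved log2 values by 0.2, so that on library size alone 7 were higher and 20 lower. The inflammation-induced list had 5 of 33 members higher, 12 higher and 1 lower when adjusted over the list alone (camera adjusted p = 7.0e-04; adjusted p = 0.85 with an estimated correlation; fry 0.081). The miR-23/24/27 list had 2 of 33 higher, 6 by the list alone (1.8e-07; adjusted p = 0.53 with an estimated correlation; fry 0.015), and the miR-17-92 list 5 of 40 lower by either adjustment (0.025; adjusted p = 0.85 with an estimated correlation; fry 0.41). The count was 6 and 2 without infected 6 h replicate 2 and 3, and 4, 5 and 2 without infected 24 h replicate 1, 2 and 3. In all, 2 of 10 named calls, miR-27c-5p and PC-3p-896_7198, held whichever of the 6 compared libraries was left out. When only the infected groups were fitted 3 passed, and of the named calls miR-20b-5p and PC-3p-896_7198 held. The miR-21-5p call was also lost on library size alone, and the miR-19b-3p call with RLE factors.

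The direct test asked whether the infection effect differed between the sampled times. The effect was higher at 24 h than at 6 h for miR-23a-5p, let-7h-3p, miR-27c-5p and miR-222a-3p. It was lower at 24 h for miR-363-3p, miR-19b-3p, miR-152-3p and miR-30c-5p. For miR-23a-5p and let-7h-3p the effects were log2 -0.21 and -0.3 at 6 h, neither called, and 1.12 and 0.83 at 24 h. The controls of these 2 sequences changed by -0.69 and -0.82 between the times. miR-27c-5p had an infection effect of log2 0.52 at 6 h and 1.57 at 24 h, a difference of 1.05 ± 0.19 (SE, edgeR adjusted p = 0.023). miR-363-3p had 0 and -1.84, a difference of -1.85 ± 0.39 (0.04). In edgeR's test 12 sequences passed (7 higher, 5 lower; 91 at an unadjusted p under 0.05), TMM moved the differences by 0.14, and 5 were higher and 8 lower on library size alone. With a replicate block 0 passed in edgeR (92 at an unadjusted p under 0.05). The miR-23/24/27 list had 2 of 33 members higher, 3 by the list alone (camera adjusted p = 0.0074; adjusted p = 0.87 with an estimated correlation; fry 0.12), and the list of miR-148 and miR-152 had 1 of 6 lower, 4 when adjusted over the list alone (0.0074; adjusted p = 0.87 with an estimated correlation; fry 0.12). miR-155-5p (1.95, adjusted p = 0.086) and miR-21-5p (0.65, adjusted p = 0.38) did not pass this test. None of the 9 named calls held whichever of the 12 libraries was left out. The count was 0 in edgeR without control 6 h replicate 1 or 3, control 24 h replicate 2, infected 6 h replicate 2 or 3 or infected 24 h replicate 3 (70 to 105 at an unadjusted p under 0.05; DESeq2 called 41), 5, 4, 5 and 3 without control 6 h replicate 2, control 24 h replicate 1 and infected 24 h replicate 1 and 2, and 22 without control 24 h replicate 3.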

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

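The tests of drift between the control groups and of the scaling were chosen only after the result was seen. In 12 sequences the infection effect differed between 6 h and 24 h in edgeR's quasi-likelihood test of the difference itself (Benjamini-Hochberg adjusted p from 0.023 to 0.049). With a replicate block 0 of the 12 were called (edgeR, 92 sequences at an unadjusted p under 0.05; without the block DESeq2 called 41). The effect at 24 h was higher by log2 1.33 for miR-23a-5p, 1.12 for let-7h-3p, 1.05 for miR-27c-5p, 0.95 for miR-222a-3p, 1.28 for miR-4286-5p and 1.78 for miR-9226-5p. It was lower, with differences of -1.86 for PC-3p-896_7198, -1.85 for miR-363-3p, -1.59 for miR-19b-3p, -0.78 for miR-30c-5p and -0.76 for miR-152-3p. PC-5p-13606_129 had a fitted difference of 6.17, which is no bound, since it had 0 counts in the control 24 h libraries (11, 25 and 28 counts in control 6 h, 51, 22 and 33 in infected 6 h, 14, 11 and 5 in infected 24 h).

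The tables argue against TMM scaling as the whole cause of the higher sequences, since on library size alone 5 of the 7 were still called. TMM moved the differences upward by 0.14, so the lower sequences could only become more extreme without it. That 5 of these 5 were still called is therefore no test. Drift between the control groups cannot be told apart from a changed response: the controls' own change between the times made up a median share of 0.52 of the difference in the higher sequences (quartiles 0.14 and 0.7) and 0.34 in the lower ones (quartiles 0.14 and 0.58). For let-7h-3p the share was 0.73 and for miR-23a-5p 0.52, but for miR-27c-5p it was 0.04, so this sequence may be the better place to look for a response that grows with time, which stays a hypothesis. It was 0.11 for miR-222a-3p, whose call was lost on library size alone. Chance is not excluded, and the drawn splits cannot decide on it. In 5 of 100 drawn splits of the 12 libraries, the real one included, at least 12 sequences were called, with 61 in the highest. The 4 larger splits, with 24 to 61 calls, all exchanged the infected and control labels of 24 h as whole groups, a structure of the design. They thus carry the real 24 h difference and are no measure of chance alone. The 1 with 61 calls kept the 6 h groups whole and so contrasts the sum of both infection effects, while the others mixed infected and control libraries of 6 h.

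For the other comparisons the 10 splits of 6 libraries are too few to give a share under 0.05, and in each the real split was the 1 with as many calls. The real splits gave 5 calls in edgeR at 6 h (highest other 1), 89 at 24 h (highest other 7), 11 in controls over time (highest other 0) and 19 in infected fish over time (highest other 0).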

How the results depend on the processing

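Summing the entries of a sequence and keeping sequences with identical counts once were alternatives chosen after seeing the data. No named call changed sign under any alternative run. The 24 h count stayed within 1.5 times of 89 under the other tests and scalings, with 88 of the 89 also called by DESeq2, 82 by limma-voom, 88 by limma on the authors' normalised values and 67 on library size alone, where fewer rises and more falls passed because TMM moves all log2 values by 0.21. Depth limits the least abundant sequences: a count of 0 allows up to 3 counts per library. Small counts of calls moved most, and apart from fewer sequences tested or fewer libraries the cause was not tested.

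DESeq2 called 30 sequences at 6 h, 56 in controls over time, 40 in infected fish over time and 41 for the difference of effects, with 16 shared between the infection comparisons; the odds ratio of predicted against known miRNAs at 24 h turned to 0.96 (Fisher's exact p = 1). On library size alone 19 passed in controls. With at least 10 CPM, 9 passed at 6 h and 26 in controls, and the odds ratio of predicted against known miRNAs at 6 h was 8.14 (Fisher's exact p = 0.016). Fits of the compared groups alone called 3 at 6 h, 45 at 24 h, 0 in controls (edgeR, 73 at an unadjusted p under 0.05) and 3 in infected fish. Entries as deposited gave 23 in controls. Summing end variants, which also pools the loci of an arm, gave 3 at 6 h and 2 lists at 24 h. Known miRNAs alone gave 3, 59 and 17 at 6 h, at 24 h and in controls. With an estimated correlation camera called 0 lists at 6 h and 0 at 24 h, and fry 0 at 6 h, where camera with the preset correlation called 3 and 5.

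Whether libraries of a replicate number belong together stays open: deviations from the group means correlated between same-numbered libraries by -0.29 to 0.25 (median 0.01), with 6 of 18 pairs over 0.1, and 5 of 12 libraries correlated best with their own number. Between 6 h and 24 h the control pairs had 0.19, 0.25 and 0.11, and the infected pairs -0.29, -0.07 and -0.12. A replicate block gave 16 calls at 6 h, 75 at 24 h, 12 in controls, 18 in infected fish and 0 for the difference of effects (edgeR, 92 at an unadjusted p under 0.05; without the block DESeq2 called 41), with 8 shared between the infection comparisons.

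Leaving out each library of the compared groups in turn (the others of the 12 were kept) gave 3 to 10 calls at 6 h, 40 to 104 at 24 h, 0 to 39 in controls, 2 to 18 in infected fish and 0 to 22 for the difference of effects, 3 to 9 shared sequences, and 2 to 5 lists at 6 h. The value of miR-462 at 6 h, log2 0.01 and not called, turned to -0.06 on library size alone, 0 without a filter, -0.03 with at least 10 CPM, -0.05 with end variants summed, -0.01 with entries summed and 0 with identical counts kept once, and ranged from -0.09 to 0.07 when libraries were left out.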

Other observations

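The tests of several loci and of a swapped label were chosen only after the result was seen. Among the miRNAs that fell at 24 h, 4 sequences, grouped after they were called, lie together in the genome; they are 3 miRNAs and a form of miR-363-3p with 1 more base. miR-18a-5p, miR-20b-5p, miR-363-3p and PC-3p-896_7198 sit within positions 16285689 to 16286860 on the plus strand of scaffold NW_017859641.1, as the authors' table places them, and all 4 were called lower under TMM, RLE factors and library size alone. The 20 sequences of the other miR-17-92 loci, on scaffolds NW_017859645.1 and NW_017859656.1, had log2 fold changes from -0.8 to 0.83 with a median of -0.13, and 3 were higher and none lower (1 and 0 with RLE factors, 1 and 3 on library size alone). miR-19b-3p, which was called lower with -1.66 (edgeR adjusted p = 0.0019), has no position in the authors' table and is in neither group. A shorter miR-20b-5p form placed elsewhere, on the minus strand of scaffold NW_017859685.1, fell as well, with -1.84 (edgeR adjusted p = 0.0081); its bases are also contained in the miR-20b-5p of the 4, so its locus stays open.

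The rises of miR-21-3p, of the 5p side of a miR-29 hairpin and of miR-128-5p gave the hypothesis that infection may raise the less abundant arm of a hairpin more than the abundant one. Counting noise and such a preference cannot be told apart: of 17 hairpins with a called rise of the abundant arm at 24 h, 8 had the lesser arm above it (mean gap log2 0.26, SD 1.23, exact two-sided sign-flip p = 0.48), but choosing hairpins by that rise lowers the gap and leaves out those of miR-29 (gap 3.11) and miR-128 (2.52). The 17 hairpins hold 15 distinct abundant arms, so the sign-flip test counts some values more than once. The lesser arm lay above in 63 of 119 hairpins whose abundant arm was not called (median gap 0.03) and in 11 of 13 whose abundant arm was lower (0.33). Whether several loci that share an abundant arm dilute its rise cannot be told apart, since the 3 hairpins with a single locus had a median gap of 0.1 and the other hairpins with such a rise -0.08, both within that SD; the rule that a gap within its SD decides nothing was set after a first run of this test.

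Infected 6 h replicate 1 lies between its own group and the infected 24 h libraries. A response score, the mean log2 CPM of 29 sequences minus that of 16 sequences that were called higher and lower in a fit of the 24 h libraries alone, was -0.3 in it, -0.83 and -1.12 in the other infected 6 h libraries, 1.1 to 1.4 in the infected 24 h libraries and -1.69 ± 0.1 (SD, n = 3) in the 6 h controls. When each infected 24 h library in turn was left out of the choice of sequences, that library still scored above it by 1.11 to 2.11, more than the SD of the infected 24 h libraries (0.26 to 0.46), which argues against a swap with one of them; on the first principal component its gap of 2.94 to the lowest of them lies within their SD of 5.3 and decides nothing. Greater depth stays partly open: thinning to the lowest library total, 9146931 counts, left the score at -0.3, still above -0.83 and -1.12. A score of relative levels hardly responds to thinning, so the number of counts alone did not raise it. Thinning tests nothing else that may go with a deeper library. No biological explanation was tested, and a faster course of infection in this sample could not be tested with these labels.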
